A study of Mus musculus with 6 samples.

How the data were processed

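Total RNA was measured on 6 Affymetrix arrays, 1 per sample, from BCR-ABL1-transformed pre-B cells of mice labelled as Blnk knockout. Per the labels, the mice were of the Balb/c strain and 4 weeks old, RNA was extracted with a Qiagen RNeasy kit and labelled with biotin, and GFP-positive cells were sorted 5 days after transduction. The groups came from the transduction label: 3 samples received pMIG, a retroviral vector that carries GFP, and 3 received Blnk. The replicate numbers 1 to 3 came from the sample titles. The labels do not say what these numbers stand for, nor whether the samples of a group came from separate cultures or animals, so the p-values measure only the spread between these samples, which may be technical.

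The deposited values are intensities on a linear scale, as whole numbers from 3 to 22187 per probe. RMA is named in the submitters' processing notes, and its version is not given in the sources used here. RMA gives log2 values, and the whole numbers look like RMA values returned to the linear scale and rounded, which is inferred from the values alone. The test had been planned for log2 values as deposited. Because the deposited intensities were linear, log2 was taken before any test, with nothing added. Rounding makes steps between values large for dim probes: 13.7% to 14.1% of the probes of an array lay below an intensity of 16. The median intensity was between 67.0 and 70.0 on every array. The number of arrays limits the precision of each value.

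Probes were named from the platform annotation table. Of 35421 probes, 21789 had 1 gene symbol, 1621 had several and 12011 were not listed. Entrez identifiers of 21698 single-gene probes matched a gene table of the GRCm38.p6 assembly, which was used for names only, and no symbol needed an update. Each gene was represented by its brightest single-gene probe over the 6 arrays, which gave 19938 genes, of which 999 had more than 1 such probe. Probes with several symbols or none entered no gene test. A probe can also pick up transcripts of close relatives of its gene, so members of gene families such as Vpreb1 and Vpreb2, Gimap, Ifit and the major histocompatibility genes are less certain than others.

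Blnk and pMIG samples were compared with lmFit and eBayes of limma 3.58.1 in R 4.3.3, with the group as the only term, the default variance prior, no filter on dim genes and no further normalization. Adjusted p-values are Benjamini-Hochberg values over all 19938 genes, with a threshold of 0.05, no fold minimum and two-sided tests. Fold changes are differences of mean log2 intensity, Blnk minus pMIG, and errors are standard errors (SE) of limma, or standard deviations (SD) of linear intensities with n = 3. Gene lists were tested with limma's camera with a preset inter-gene correlation of 0.01, adjusted over 30 lists. Camera with an estimated correlation, and fry, which asks whether the genes of a list move on balance one way without comparing them with other genes, were alternatives.

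The 30 lists, the rule for naming genes and all but the alternatives named below were fixed before the data were examined. The lists covered pre-B cell receptor components, pre-BCR proximal signalling, BCR inhibitory receptors and phosphatases, BCL6 and quiescence, FOXO1 and FOXO3 targets, V(D)J recombination, small pre-B and light-chain genes, B-lineage transcription factors, pro-B and progenitor genes, targets of IL7R, ABL and STAT5, MYC targets, G1/S and DNA replication, G2/M and mitosis, immediate-early and calcium-NFAT response, NF-kB targets, apoptosis regulators, p53 targets, interferon-stimulated genes, adhesion and chemokine receptors, immature and mature B markers, plasma cell and secretory genes, glycolysis, cholesterol biosynthesis, amino acid and one-carbon metabolism, ribosomal proteins, oxidative phosphorylation, and markers of T and NK cells, myeloid cells, erythroid cells and megakaryocytes, and stromal and endothelial cells. Of 673 list entries, 621 were measured, 3 of them through a synonym. Igkc and Lyn were not analysed here.

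The rule named Blnk itself, the 12 genes with the largest rise and the 12 with the largest fall among genes past the threshold with separate groups (leaving out placeholder names and immunoglobulin variable segments), 17 genes of pre-B cell biology whatever their values, up to 4 members of each list with the smallest adjusted p, and for markers of other cell types the 2 members with the highest mean level. Of the list members under this rule, those past the threshold were followed through the alternatives, and lists were followed only where they passed with the preset correlation. Both restrictions were made after the data were seen. Members named beyond the rule, and all genes of the last observations, were also chosen after their values were seen.

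The alternatives fixed in advance were the replicate number as a block, quantile normalization repeated, arrays centred on their medians, genes below the 40th percentile of mean level left out, the mean of all probes of a gene, a trended and robust variance prior, array weights, each array left out, a fold minimum of 2, an adjusted p under 0.01, all probes tested without collapsing, and both other list tests. Taking log2 of intensity plus 16, and testing families of gene symbols for enrichment, were added after the data were seen.

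The procedure was tested on 1 simulated set of 19938 genes for the Blnk against pMIG comparison. Of the genes shifted by 0.5, 1 and 2 on the log2 scale, 43.3%, 86.6% and 98.5% were recovered. Of 157 genes called, 5 (3.18%) were unchanged ones. Camera recovered the 1 list that had been shifted and called 0 of the others. The simulated genes were drawn independently of each other, so this says nothing about list calls where genes are correlated. Fewer genes were shifted than were called in the data, and variances were drawn without regard to level. The shares recovered may therefore differ in the data. Plots were drawn with matplotlib 3.10.9.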

Results

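Gene expression was measured in pre-B cells that had been transformed by BCR-ABL1, the fusion kinase of Philadelphia chromosome-positive leukemia, and that are labelled as knockout for Blnk (also called Slp65), an adaptor that links the pre-B cell receptor to its downstream enzymes. Cells transduced with Blnk (3 samples) were compared with cells transduced with the empty vector pMIG (3 samples), so the comparison asks how adding Blnk changes the transcripts of these cells. Median array intensity was 67.0 to 69.0 in the pMIG samples and 69.0 to 70.0 in the Blnk samples. Arrays of the same group correlated at r = 0.9951 or more across genes, which are not independent replicates. The first principal component, with 45.7% of the variance, separated the groups.

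Blnk transcript was higher in every Blnk sample than in any pMIG sample. Its intensity was 970 ± 43.5 (SD, n = 3) with pMIG and 3026 ± 314 (SD, n = 3) with Blnk, a 3.11-fold rise (log2 fold change 1.64, SE 0.0914; limma adjusted p = 0.000101). On the log2 scale the single arrays stood at 9.92, 9.85 and 9.98 with pMIG and at 11.41, 11.71 and 11.56 with Blnk. The signal in the pMIG samples was itself well above the array medians. Which part of Blnk the probe reads, and whether the knockout removes that part, is not given in the sources used here, so the pMIG level does not check the genotype.

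More genes were higher with Blnk than lower. In all, 720 of 19938 genes changed, 500 up and 220 down, and 79 rose and 29 fell by 2-fold or more. Fcmr, the Fc receptor for IgM, rose most, from an intensity of 69.3 ± 5.51 to 1896 ± 257 (SD, n = 3), and Jchain, which joins the units of secreted IgM and IgA, rose from 38.3 ± 8.02 to 435 ± 103. Of the genes that fell, Sytl2, a vesicle transport protein, dropped from 310 ± 33.5 to 62.3 ± 7.51, and Erg, an ETS transcription factor of early progenitors, from 599 ± 23.5 to 158 ± 5.13. All 720 changed genes had separate groups, which the threshold largely brings about with 3 arrays per group. In total 3981 genes had separate groups (19.97%, where chance gives 10%). Repeating quantile normalization gave 738 genes with a different balance, 411 up and 327 down. Leaving out 1 array lowered the count to 375 (without pMIG 1), 368 (without pMIG 2), 267 (without pMIG 3), 437 (without Blnk 1), 319 (without Blnk 2) and 315 (without Blnk 3). Fewer arrays weaken the test by construction, so a gene that no longer passes may keep its fold change.

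**Figure D1:**
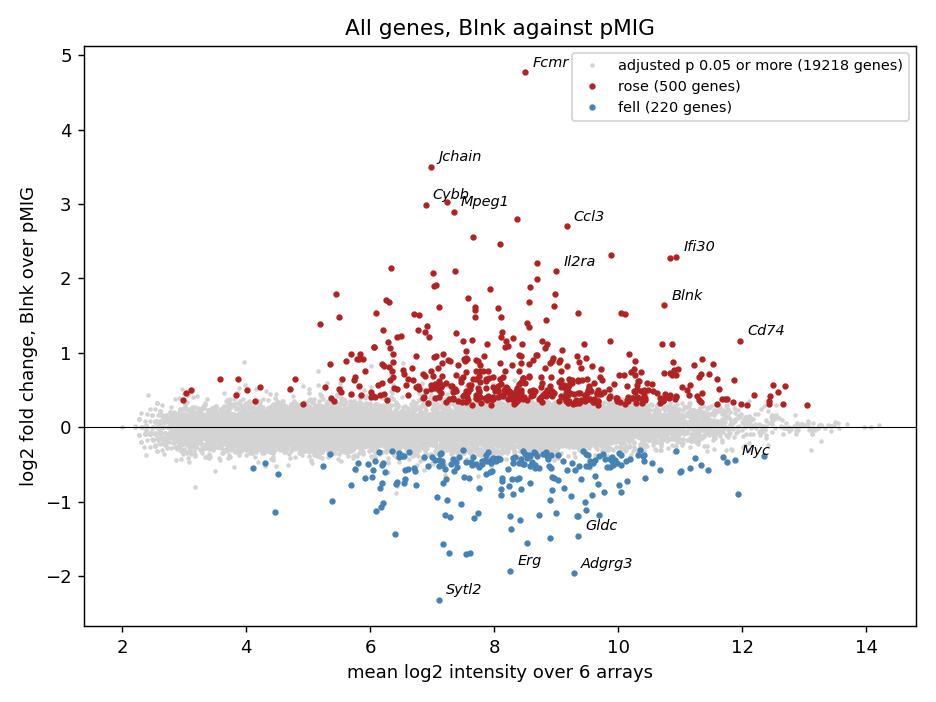
Log2 fold change (Blnk over pMIG, vertical axis) against mean log2 intensity over the 6 arrays (horizontal axis), 1 point per gene, with 500 genes that rose in red and 220 that fell in blue. Fcmr lies highest at 4.77 and Sytl2 lowest at -2.32.

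Besides Fcmr (4.77) and Jchain (3.50), the largest log2 rises were those of Cybb (2.99), the catalytic subunit of the phagocyte NADPH oxidase, Mpeg1 (2.89), a perforin-like protein, Rassf4 (2.80), the chemokine Ccl3 (2.70), Fcrl5 (2.56), an Fc receptor-like protein of B cells, and Ly86 (2.46), the partner of a Toll-like receptor relative on B cells. They were followed by Pim2 (2.31), a survival kinase, Ifi30 (2.29), a lysosomal thiol reductase used in antigen processing, Ly6d (2.27), a surface marker of B-lineage commitment, and Cfp (2.21), properdin of the complement system. Adjusted p of these 12 genes lay between 3.65e-06 (Fcmr) and 0.000125 (Jchain), and each remained past the threshold with any 1 array left out.

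The largest log2 falls were those of Sytl2 (-2.32), Adgrg3 (-1.96), Erg (-1.92), the vault RNA Vaultrc5 (-1.70), Mc1r (-1.69), Megf10 (-1.68), Slc7a3 (-1.57), a carrier of cationic amino acids, and Rgcc (-1.55). Bfsp2 (-1.49), Gldc (-1.46), an enzyme of glycine breakdown, Trgv1 (-1.43), a T cell receptor gamma variable segment, and Adgrg1 (-1.36), like Adgrg3 an adhesion G protein-coupled receptor, completed the 12. All but Vaultrc5 passed with every array left out. Vaultrc5 (adjusted p = 0.0102) did not pass without pMIG 1 (0.0703), pMIG 2 (0.0569), pMIG 3 (0.0508) or Blnk 3 (0.0747). Placeholder names and immunoglobulin variable segments made up 17 of the genes that rose and 6 of those that fell.

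Markers of immature and mature B cells moved furthest of the 30 lists. Of 23 measured members, 16 rose and 0 fell (18 rose when adjusted over the list alone), with a median log2 fold change of 0.68. Genes of antigen presentation were among them: H2-Aa, a class II chain, rose from 284 ± 21.9 to 882 ± 48.0 (SD, n = 3) and Cd74, the invariant chain, from 2663 ± 28.3 to 5981 ± 515. Bank1, a B-cell scaffold protein, rose by 1.12 and the costimulatory receptor Cd40 by 1.27 on the log2 scale. The list passed with camera (adjusted p = 9.63e-22) and not with the correlation estimated from the data (adjusted p = 0.154 with an estimated correlation). Without pMIG 3 or without Blnk 2, 10 members rose.

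Genes of proximal receptor signalling, in the pathway that Blnk itself belongs to, rose in part. Of 20 measured members, 7 rose and 0 fell (10 rose and 1 fell when adjusted over the list alone), median 0.24. Rasgrp3, an activator of RAS, rose from 68.7 ± 2.08 to 259 ± 7.21 (SD, n = 3), and Blk, a SRC-family kinase of B cells, from 1393 ± 38.0 to 2573 ± 162. The adaptor Lat2 rose by 1.22 and Bank1 by 1.12 on the log2 scale. Camera gave adjusted p = 6.95e-09 (adjusted p = 0.251 with an estimated correlation). Inhibitory receptors and phosphatases of the same pathway also rose in part: 4 of 14 rose and 0 fell (8 rose when adjusted over the list alone), median 0.28, camera adjusted p = 9.60e-09 (adjusted p = 0.154 with an estimated correlation). Cd72 rose by 0.63, Pecam1 by 0.64, the phosphatase Ptpn22 by 0.90 and the inhibitory Fc receptor Fcgr2b by 0.51. Without pMIG 3, 2 of these 4 passed. Ptpn22 did not pass without pMIG 3 (0.0589), Blnk 1 (0.0668) or Blnk 3 (0.0661), nor Fcgr2b without pMIG 3 (0.0529) or Blnk 2 (0.0505).

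Components of the pre-B cell receptor did not move together: of 7 measured, 1 rose and 1 fell (3 and 3 when adjusted over the list alone), and the list did not pass (camera adjusted p = 0.721; median 0.14 and mean -0.01 differ in sign). Vpreb1, a surrogate light chain, fell from 1746 ± 122 to 1090 ± 116 (SD, n = 3; adjusted p = 0.00976), and did not pass without pMIG 2 (0.0502) or pMIG 3 (0.0688). Its near-identical relative Vpreb2, named after its value was seen, stood at -0.22 (adjusted p = 0.157), and one probe may read both. Cd79a, a signalling chain of the receptor, rose by 0.31 (adjusted p = 0.0468), with adjusted p of 0.0678 (without Blnk 1) to 0.151 (without pMIG 3) whichever array was left out. Igll1 stood at -0.19 (adjusted p = 0.227) and Ighm at 0.14 (adjusted p = 0.397). Ighm was dim, at 67.3 ± 1.53 and 74.3 ± 3.51 (SD, n = 3), close to the array medians, so little can be said about its change. Igll1 was bright, at 10485 ± 350 and 9221 ± 222.

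Genes of the small pre-B stage and of light-chain opening rose in part, with 7 of 16 up and 0 down (8 up and 1 down when adjusted over the list alone), median 0.18 (0.31 with dim genes left out), camera adjusted p = 7.62e-07 (adjusted p = 0.251 with an estimated correlation). Il2ra (CD25), the surface marker of this stage, rose from 248 ± 25.3 to 1065 ± 161 (SD, n = 3; log2 2.09, adjusted p = 0.000131). Spib, an ETS factor of B cells, rose by 1.12, Cd74 by 1.16 and the transcription factor Klf2 by 0.96, each with every array left out. Irf4 rose by 0.40 (adjusted p = 0.0164) and Ikzf3 (Aiolos) by 0.39 (adjusted p = 0.0447). Irf4 passed without pMIG 2 (0.0483) and with no other array left out, up to 0.0838 without pMIG 3, and Ikzf3 with none, from 0.0656 without Blnk 1 to 0.146 without Blnk 3. Irf8 (-0.21, adjusted p = 0.155) and Ikzf1 (0.13, adjusted p = 0.489) did not pass. Neither did the recombinase genes Rag1 (0.08, adjusted p = 0.832) and Rag2 (-0.33, adjusted p = 0.303), which were dim, with intensities of 29.7 ± 4.16 and 16.3 ± 2.08 in the pMIG samples. Of 13 genes of V(D)J recombination, 0 rose and 0 fell by limma, also when adjusted over the list alone, with 0 higher and 1 lower at an unadjusted p under 0.05 (camera adjusted p = 0.545, fry 0.557).

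**Figure D2:**
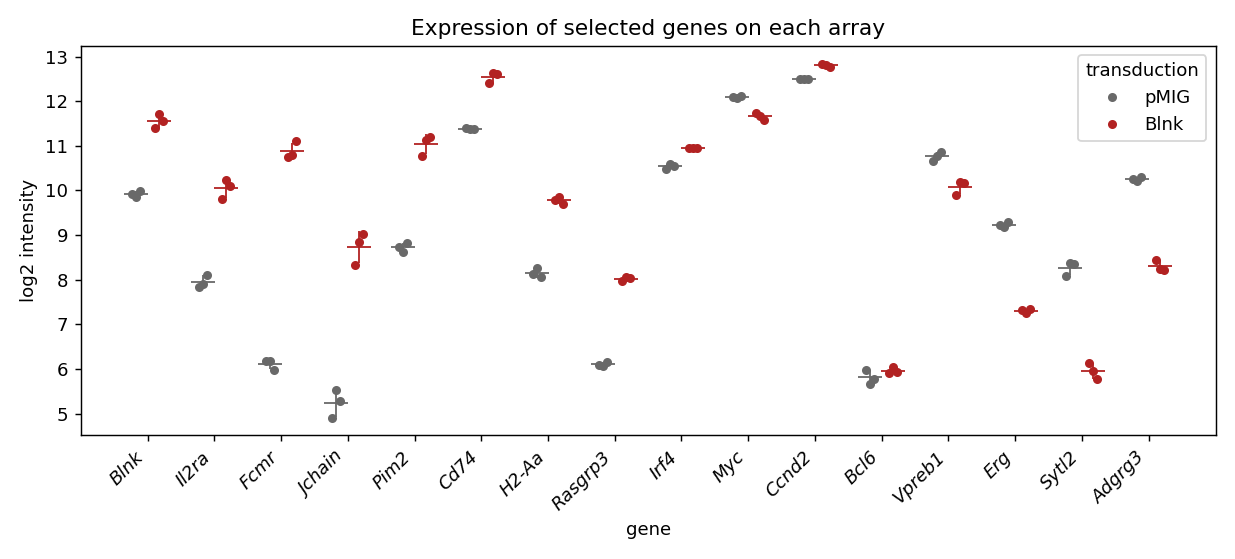
Log2 intensity (vertical axis) of 16 genes (horizontal axis) on each of the 3 pMIG arrays (grey) and 3 Blnk arrays (red), 1 point per array, with the mean as a horizontal mark and the SD as a bar. Fcmr rose by 4.77 and Erg fell by 1.92 on the log2 scale, while the pMIG and Blnk arrays overlapped for Bcl6, which stood at 0.15.

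Among transcription factors of the B lineage, 2 of 20 rose and 2 fell (4 and 6 when adjusted over the list alone; camera adjusted p = 0.700, median 0.01 and mean -0.07), and the list passed downward with fry (adjusted p = 0.0465). Besides Erg and Ikzf3, Pou2f2 (OCT2) rose by 0.48 and Lef1, a WNT effector of early B cells, fell by 0.48. Without pMIG 3, neither Pou2f2 (0.0582) nor Lef1 (0.0540) passed, and Ikzf3 passed with no array left out. Erg and Lef1 were also the 2 of 16 pro-B and progenitor genes that fell, with 0 up (0 up and 4 down when adjusted over the list alone; camera adjusted p = 0.0711, passing without Blnk 3 at 0.0369, and passing downward with fry at 0.00415). Il7r stood at -0.07 (adjusted p = 0.678).

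The quiescence list, built around the repressor BCL6, had 5 of 17 members up and 0 down (7 up when adjusted over the list alone), with a median of 0.08 that lay at -0.0031 without Blnk 3, 0.02 without pMIG 1, 0.12 without pMIG 3 and 0.13 without Blnk 1, at 0.02 after quantile normalization and at 0.04 with array weights. It had 3 up without any 1 pMIG array, Blnk 2 or Blnk 3. Camera gave adjusted p = 0.00524 (adjusted p = 0.497 with an estimated correlation), 0.0655 without pMIG 1 and 0.0639 without dim genes, and fry gave adjusted p = 0.0590. The members that rose included Klf2 (0.96) and the antiproliferative genes Btg1 (0.67), Pdcd4 (0.71) and Btg2 (0.93). Btg2 passed only without Blnk 1 (0.00675) among the arrays left out, up to 0.110 without Blnk 2. Bcl6 itself was dim, at 56.3 ± 6.11 and 62.3 ± 3.21 (SD, n = 3), and did not pass (0.15, adjusted p = 0.528), nor did the cell cycle inhibitor Cdkn1b (0.02, adjusted p = 0.933). Of 22 targets of FOXO1 and FOXO3, 4 rose and 2 fell (4 and 4 when adjusted over the list alone; camera adjusted p = 0.896, median -0.01 and mean 0.02). Klf2 and the stress protein Sesn3 (0.50) rose with every array left out. The chemokine receptor Ccr7 rose by 0.70, but not without pMIG 1 (0.060), pMIG 3 (0.0768) or Blnk 2 (0.0714), and Bnip3 fell by 0.87, passing only without Blnk 3 (0.00862) and reaching 0.115 without pMIG 3. Of these targets 2 rose without pMIG 1, pMIG 3 or Blnk 2, and 1 fell without Blnk 3 and 0 without any other array.

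Targets of IL7R, ABL and STAT5 signalling went both ways: of 24, 8 rose and 2 fell (9 and 8 when adjusted over the list alone), with a median of -0.10 and a mean of 0.21, and the list did not pass with camera (adjusted p = 0.538), though it did upward with fry (adjusted p = 0.0246). Without pMIG 3, 2 members rose, 3 without Blnk 2, 4 without pMIG 2, Blnk 1 or Blnk 3, and 5 without pMIG 1. Without Blnk 1, 2 fell, and 0 without any other array. Pim2 (2.31) and Il2ra (2.09) rose with every array left out. Pim1, a survival kinase, rose by 0.71 and the feedback inhibitor Cish by 0.85. Pim1 did not pass without pMIG 3 (0.0528) or Blnk 2 (0.0537), nor Cish without pMIG 3 (0.0633) or Blnk 2 (0.0615). Myc fell from 4386 ± 76.9 to 3240 ± 192 (SD, n = 3; log2 -0.44, adjusted p = 0.0161), passing only without Blnk 1 (0.0307) among the arrays left out and reaching 0.0914 without pMIG 3. Of 34 MYC targets, 1 rose and 1 fell (2 and 1 when adjusted over the list alone), these being Ccnd2 and Myc itself, with a median of -0.11 (-0.17 without Blnk 1, -0.07 without Blnk 3). The list passed downward with camera (adjusted p = 0.00524), not without Blnk 3 (0.225) and not with fry (adjusted p = 0.390; adjusted p = 0.699 with an estimated correlation).

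Cell cycle genes moved little. Of 37 genes of G1/S and DNA replication, 1 rose, Ccnd2 (0.31, adjusted p = 0.0392), and 0 fell (1 and 3 when adjusted over the list alone; median -0.04). With any array left out Ccnd2 did not pass, from 0.0907 (without pMIG 1) to 0.144 (without pMIG 3). Ccnd3 stood at -0.28 (adjusted p = 0.0870). Of 33 genes of G2/M and mitosis, 1 rose, Nek2 (0.33), and 0 fell (1 and 0 when adjusted over the list alone; median -0.05). Nek2 did not pass with any array left out, from 0.0531 (without Blnk 1) to 0.147 (without pMIG 3). Neither list passed with camera (adjusted p = 0.164 and 0.0822). Without Blnk 1 both passed downward (0.000685 and 0.00699), and the mitosis list did so without pMIG 1 (0.00752).

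NF-kB targets rose in part, with 9 of 21 up and 0 down (14 up when adjusted over the list alone), median 0.30, camera adjusted p = 1.72e-13 (adjusted p = 0.154 with an estimated correlation). Ccl3 rose from 227 ± 26.8 to 1471 ± 103 (SD, n = 3), Cd40 by 1.27, and the pathway members Nfkbie and Nfkb2 by 0.97 and 0.69 on the log2 scale. Without pMIG 3, 4 members passed, and 5 without Blnk 2 or Blnk 3. Genes of the immediate-early and calcium-NFAT response moved both ways, with 6 of 29 up and 2 down (7 and 2 when adjusted over the list alone), median 0.16 (0.31 without Blnk 1), camera adjusted p = 0.00185 (adjusted p = 0.373 with an estimated correlation). Nfatc1, a calcium-regulated factor, rose by 0.57 and Egr2 by 0.65, and Fosb fell by 0.82. Egr2 did not pass without pMIG 3 (0.0520) or Blnk 2 (0.0556), nor Fosb without pMIG 3 (0.0571), Blnk 1 (0.0601) or Blnk 3 (0.0552). Without pMIG 3, 2 members rose and 0 fell. Without pMIG 2, Blnk 2 or Blnk 3, 3 rose, and without Blnk 1 or Blnk 3, 1 fell.

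Receptors of adhesion and migration had 8 of 23 members up and 0 down (10 up when adjusted over the list alone), median 0.22, camera adjusted p = 2.89e-06 (adjusted p = 0.251 with an estimated correlation). The chemokine receptors Cxcr5 (0.90) and Ccr6 (1.27) and the cannabinoid receptor Cnr2 (0.99) rose with every array left out. Ccr9 rose by 0.85, but not without pMIG 1 (0.0601), pMIG 3 (0.0742) or Blnk 2 (0.0668). Ccr9 was dim, at 30.7 ± 2.89 and 55.7 ± 8.62 (SD, n = 3). Without pMIG 3 or Blnk 2, 3 members rose, 4 without pMIG 1, and 5 without pMIG 2 or Blnk 3. The plasma cell and secretory list had 6 of 18 up and 0 down (10 up when adjusted over the list alone), median 0.27, camera adjusted p = 3.26e-08 (adjusted p = 0.154 with an estimated correlation). Jchain (3.50) and the elongation factor Ell2 (0.87) rose with every array left out, and these made up all 2 that passed without pMIG 1, pMIG 3 or a Blnk array. Xbp1, a factor of the secretory state, rose by 0.41 and passed only without pMIG 2 (0.0474), reaching 0.130 without pMIG 3.

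Genes of glucose and amino acid use fell in part. In the glycolysis list 0 of 18 rose and 3 fell (0 and 9 when adjusted over the list alone), median -0.23, camera adjusted p = 6.51e-07 (adjusted p = 0.338 with an estimated correlation). Those that fell were Pdk1 (-0.67), an inhibitor of pyruvate dehydrogenase, the lactate carrier Slc16a1 (-0.41) and the phosphofructokinase Pfkl (-0.54). In the amino acid and one-carbon list 0 of 18 rose and 5 fell (0 and 7 when adjusted over the list alone), median -0.16, camera adjusted p = 1.93e-06 (adjusted p = 0.290 with an estimated correlation), among them the glutamine carrier Slc1a5 (-0.47), Trib3 (-0.42), Aldh18a1 (-0.37) and asparagine synthetase Asns (-0.40). These calls did not all hold with 1 array left out. Without pMIG 3, 0 members of either list passed. In the amino acid list 0 passed without pMIG 2, Blnk 2 or Blnk 3 (2 without pMIG 1 or Blnk 1). In the glycolysis list 1 member fell without pMIG 1, pMIG 2 or Blnk 2. Without pMIG 3 the adjusted p was 0.0538 for Slc1a5 and 0.0588 for Pdk1. The other named members were less stable. Asns and Aldh18a1 did not pass with any array left out, up to 0.1545 (without pMIG 3) and 0.1282 (without pMIG 2). Slc16a1 passed only without Blnk 1 (0.03255), Pfkl only without Blnk 3 (0.0366), and Trib3 only without pMIG 1 (0.0454) or Blnk 1 (0.04). Fold changes of the named members kept their sign. With 1 array left out, Slc1a5 ran from -0.50 to -0.44, Pdk1 from -0.72 to -0.59 and Asns from -0.45 to -0.33.

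**Figure D3:**
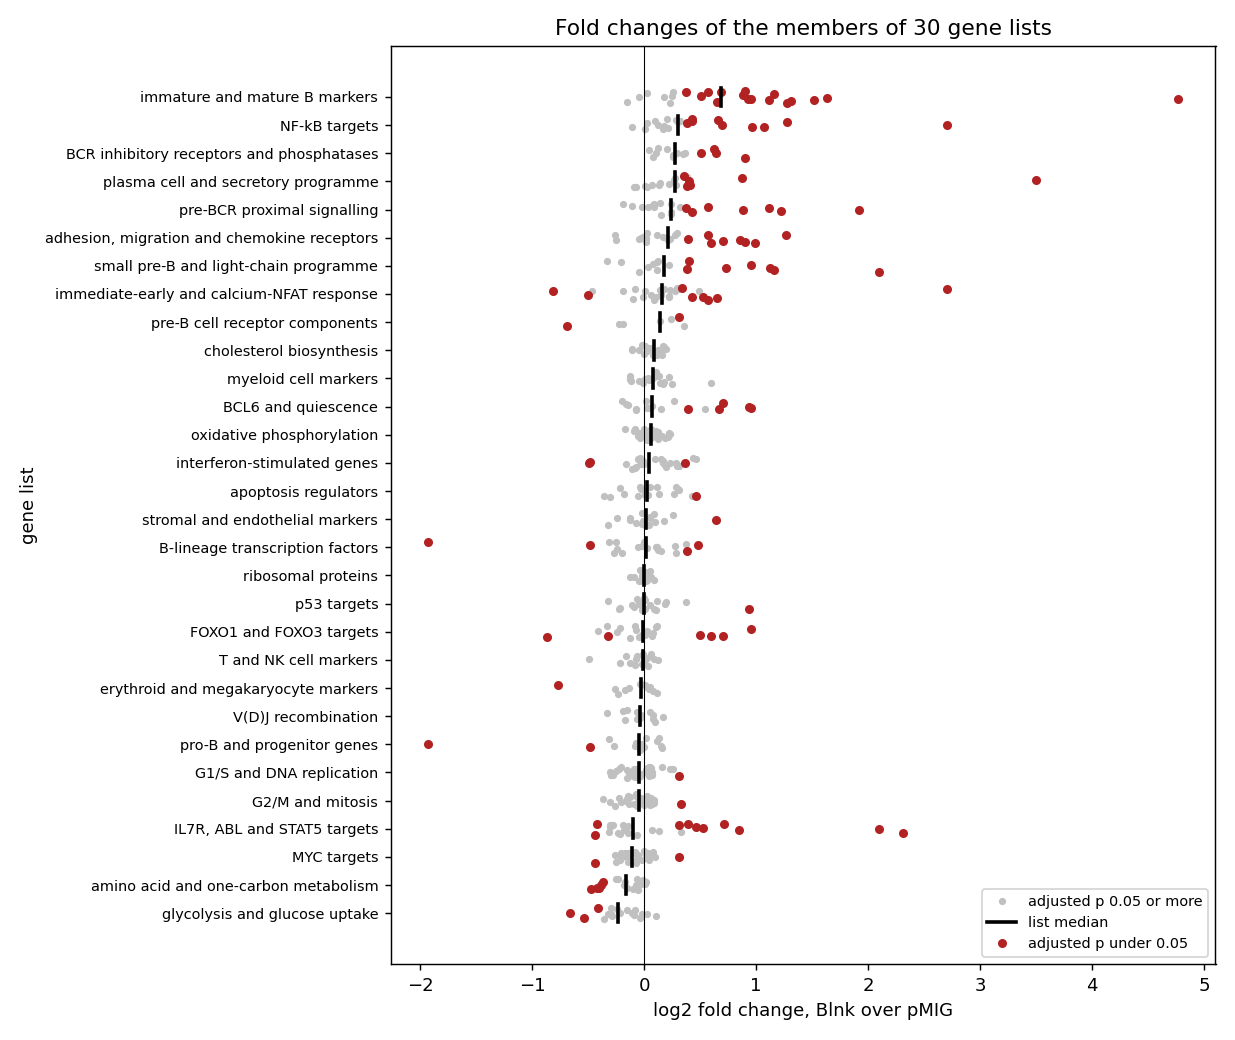
Log2 fold change (Blnk over pMIG, horizontal axis) of each measured member of the 30 gene lists (vertical axis), in red where the adjusted p was under 0.05 and in grey otherwise, with the list median as a black bar. Medians run from 0.68 for markers of immature and mature B cells down to -0.23 for glycolysis.

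The other lists held few changes and did not pass with camera. Of 26 interferon-stimulated genes, 1 rose and 2 fell (5 and 2 when adjusted over the list alone; camera adjusted p = 0.192), namely Stat2 (0.37), Ifit2 (-0.49) and Ifit1 (-0.48). Stat2 passed only without Blnk 1 (0.0456), Ifit1 only without pMIG 2 (0.0178) and Ifit2 with no array left out, from 0.0539 without Blnk 1 to 0.165 without pMIG 3. Ifit1 was dim, at 23.3 ± 2.89 and 16.7 ± 0.577 (SD, n = 3). Of 20 apoptosis regulators, Mcl1, a survival protein, rose (0.47; 4 up and 2 down when adjusted over the list alone; camera adjusted p = 0.268), though not with any array left out, from 0.0568 without pMIG 3 to 0.0990 without Blnk 3. Of 22 p53 targets, Btg2 rose (2 up and 1 down when adjusted over the list alone; camera adjusted p = 0.700), and it passed only without Blnk 1 (0.00675). No gene of cholesterol biosynthesis (18 measured), ribosomal proteins (18) or oxidative phosphorylation (23) passed by limma, also when adjusted over the list alone. At an unadjusted p under 0.05 these held 1, 0 and 3 genes that were higher and 0 that were lower, and the camera adjusted p was 0.157, 0.947 and 0.181 (fry 0.317, 0.724 and 0.400).

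Markers of other cell types moved little between the groups, and none of these lists passed with camera. Of 21 myeloid markers and of 19 T and NK cell markers, 0 rose and 0 fell by limma, also when adjusted over the list alone (1 and 0 higher, 0 and 1 lower at an unadjusted p under 0.05; camera adjusted p = 0.181 and 0.263, fry 0.272 and 0.581). Without Blnk 3, 1 T and NK cell marker fell. Cd68 stood at 93.7 ± 11.0 and 143 ± 28.3 (SD, n = 3; adjusted p = 0.0866), Tyrobp at 63.3 ± 3.79 and 70.0 ± 3.46, Cd8a at 170 ± 18.7 and 191 ± 60.8, and Zap70 at 167 ± 5.86 and 164 ± 6.66. Of 13 erythroid and megakaryocyte markers 1 fell, the carbonic anhydrase Car2 (-0.77, adjusted p = 0.00201), and Tal1 stood at -0.23 (also 1 when adjusted over the list alone; camera adjusted p = 0.181, passing without Blnk 3 at 0.0369). Of 18 stromal and endothelial markers 1 rose, Pecam1, which the list of inhibitory receptors also holds, and Col1a1 stood at -0.12 (also 1 when adjusted over the list alone; camera adjusted p = 0.577).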

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

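The probes below were tested for this part, and the bound on the share of rises was given its interval only after that share had been seen.

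Signal outside the named genes also moved with Blnk. Of 12011 probes listed under no gene, 69 rose and 18 fell, and of 1621 probes listed under several genes, 11 rose and 2 fell, in the limma fit over all 35421 probes. These probes entered no test of genes or lists. The largest log2 rise was 2.54 among probes without a gene and 2.05 among those with several. In all, 0.724% of probes without a gene and 0.802% of those with several changed, a lower share than the 1.84% of probes with 1 gene.

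The count of 720 changed genes was set against the other ways to divide the 6 arrays into 3 and 3. Of 10 splits, 1, the real one, gave 720 genes, and the highest of the others gave 0. Splits this few cannot give a share under 0.05.

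More genes rose than fell, 500 against 220, or 69.4% of the changed genes. A shift of all values left by the authors' normalization could produce such an imbalance. After quantile normalization was repeated, 55.7% of the changed genes rose, with an exact binomial 95% interval of 52.0% to 59.3% that treats genes as independent, and after centring on the medians 71.9% rose. The bound of 55%, above which a general shift was to be excluded, was set after the 69.4% had been seen and before the shares under the other 2 scalings. The value of 55.7% lies past that bound, but its interval does not, and the need to clear it with the interval was applied after the value was seen. The median log2 fold change of all genes was -5.06e-16 in the values tested, 0.0123 after centring and -0.0329 after quantile normalization. A shift of equal size in all tested genes would move this median, and the first value showed no such move. Median intensity over all probes was 67.0 to 69.0 on the pMIG arrays and 69.0 to 70.0 on the Blnk arrays. The median of the tested genes alone therefore does not settle the question. Quantile normalization itself moved the median down, so its 55.7% cannot tell a leftover shift from that move. Quantile normalization adjusts values by their level, and under it the share of rises fell from 69.4% to 55.7%. A shift that varies with level therefore stays open as part of the imbalance, beside an effect of Blnk itself. Other shifts that differ between genes were not tested.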

How the results depend on the processing

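Taking log2 of intensity plus 16 was chosen after the data were seen, the other alternatives before. The count of 720 changed genes was 289 with the replicate number as a block (287 of them among the 720), 1228 with dim genes left out, 1539 with a trended and robust variance prior, 1100 with 16 added to the intensity, 108 with a fold minimum of 2 and 312 at an adjusted p under 0.01. With 1 array left out it ran from 267 (without pMIG 3) to 437 (without Blnk 1). A smaller number of genes tested, fewer samples or a stricter criterion accounts by construction for part of these changes, and otherwise the cause was not tested. In 4 other alternatives the count stayed within 1.5 times, from 668 with arrays centred on their medians to 893 with array weights. With all probes tested, 502 probes changed, a count of probes and not of genes, of which 402 had a single gene. Samples were matched across the groups only by a replicate number. Deviations from the group means correlated at -0.187, 0.0578 and -0.12 between samples with the same number, and no sample correlated best with its own number. The largest correlation across the groups was 0.283, between pMIG 1 and Blnk 3. On the second principal component (21.6% of the variance) these stood at 16.58 and 10.98, and the other arrays below 0. What they share is not known, and no fit modelled it. The block changed neither the 12 lists called nor the call of Blnk.

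Blnk rose under all 14 alternatives run, by 1.56 to 1.71 on the log2 scale. The number of lists called was 0 with an estimated correlation, 13 with fry (10 of the 12), and 12 to 14 otherwise. Lists share members, so the 12 are not separate results: 6 of the 23 immature and mature B markers stand on another list. Many of the 119 named genes were named because they had passed, so the share that passed follows from that choice. Of the 119, 102 passed, 64 of them under every alternative and 65 with each array left out. Of the other 17, 13 passed under no alternative. Signs turned for genes that had not passed: Cdkn1b (0.02) stood at -0.020 after quantile normalization, and with 1 array left out Cdkn1b ran from -0.024 to 0.083, Rag1 from -0.036 to 0.16 and Cd8a from -0.11 to 0.36, for causes not tested. Signal over background limits dim genes: 25 of the genes that rose and 7 of those that fell lay below the 40th percentile of mean level.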

Other observations

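The genes of the first paragraphs were chosen after the full set of changed genes had been read, and the test of gene families was added then too. The test of myeloid transcripts was set after the genes with the largest changes had been seen and before its own result was.

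Some subunits of the phagocyte NADPH oxidase rose along with Cybb, and the complex was not tested as a set. Cyba, its membrane partner, rose from 1016 ± 42.0 to 1705 ± 131 (SD, n = 3) and Ncf1, a cytosolic subunit, from 128 ± 11.5 to 467 ± 53.9, while Ncf4 stood at -0.07 (limma adjusted p = 0.713). The proton channel Hvcn1, which supports the oxidase, rose by 1.16. Tlr9, a receptor for DNA in endosomes, rose by 1.08, Unc93b1, which carries such receptors there, by 0.70, and the lysosomal proteases Ctss and Lgmn by 0.79 and 0.73. Kmo and Haao, enzymes of the kynurenine route of tryptophan breakdown, rose by 2.09 and 1.21. Each of these genes that rose did so with every array left out. Other genes looked at with these were less stable. Tlr1 (0.90) passed only without Blnk 1 (0.0106), up to 0.114 without Blnk 2. Tlr7 (0.54) passed only without pMIG 1, up to 0.171 without pMIG 3. Ctsh (1.08) passed only without pMIG 2 (0.00485), up to 0.0698 without pMIG 3. Tlr7 was dim, at 15.7 ± 2.08 and 22.7 ± 1.53 (SD, n = 3), where rounding makes large steps.

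Among the genes that fell were Lat, a membrane adaptor of T cell receptor signalling, from 976 ± 8.50 to 429 ± 27.8 (SD, n = 3), and Plcg1, the phospholipase it recruits, from 631 ± 14.2 to 392 ± 16.9. The protein kinase C gene Prkch fell by 0.60. The microRNA genes Mir23a and Mir27a, neighbours in 1 cluster, fell by 1.22 and 1.19. All of these fell with every array left out. The calcium-dependent kinase gene Camk4 fell by 0.75, but not without pMIG 3 (0.0574) or Blnk 2 (0.0539). Mature microRNAs were not analysed here.

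Of 594 families of gene symbols with 5 or more measured members, tested in both directions (1188 one-sided Fisher's exact tests), only the Gimap family of small GTPases passed: 5 of 8 members rose where 0.201 would by chance (adjusted p = 0.000608). Gimap3 rose by 1.99, Gimap4 by 1.22, Gimap6 by 1.21, Gimap7 by 0.82 and Gimap8 by 0.42. Gimap8 did not pass with any array left out, from 0.0529 without pMIG 3 to 0.151 without Blnk 2. The genes lie in 1 cluster and resemble each other, so their probes are not independent.

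Cybb, Mpeg1, Ccl3 and other genes that rose are also expressed by myeloid cells, and myeloid cells in the Blnk samples could raise them. The sort for GFP would remove only cells without the vector. Such cells would bring their abundant transcripts too, and the bound set before the result was a median log2 fold change of 0.5 over Lyz2, Fcer1g, Tyrobp, Csf1r, S100a8 and Ctsg. The median was 0.107, and 0.0750 to 0.131 with 1 array left out. Lyz2 stood at 29.7 ± 1.53 and 32.0 ± 1.0 (SD, n = 3), and Fcer1g at 35.7 ± 1.53 and 38.3 ± 1.53, against a rise of Cybb from 42.3 ± 3.79 to 336 ± 15.7. Of the 21 myeloid markers 0 stood on another list, and 1 lay above the median level of all genes in the pMIG samples. Their median intensity was 35 with pMIG and 36 with Blnk. Cd68, the brightest of the 21 and not among the 6, went the other way. It stood at 93.7 ± 11.0 and 143 ± 28.3 (SD, n = 3; log2 0.59, limma adjusted p = 0.0866), and was the 1 marker higher at an unadjusted p under 0.05. Apart from Cd68, these values argue against myeloid cells as the whole source, though most of these markers were dim. Some myeloid cells are not excluded. Expression of the genes that rose within the transduced B-lineage cells stays open as a hypothesis that was not tested.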
